A study of Caenorhabditis elegans with 4 samples.

How the data were processed

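Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for MIX-1 in mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2, a population of both sexes per the labels. The samples comprised 2 ChIP libraries made with an affinity-purified rabbit polyclonal antibody against MIX-1 and 2 input libraries. Per the labels' protocols, embryos were obtained by bleaching gravid adults, crosslinked with formaldehyde and sonicated, and the immunoprecipitated DNA was ligated to indexed single-end adaptors. The labels number the replicates but do not say whether they came from separate cultures, so the spread between them may be technical.

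The deposited data used here are 3 lists of called regions, 1 for each ChIP library and 1 for the whole series. Reads were aligned with BWA to ce10, per the submitters' processing notes, and the coordinates are WormBase WS220, per the file headers. The lists of the ChIP libraries name MACS as the caller and the series-wide list names MACS v2, per the source column of the deposited files. The caller's parameters, the control library set against each ChIP library and the way the ChIP libraries were brought together in the series-wide list are not given in the sources used here. Each region of the deposited lists has a first and a last base, which are positions and not measurements, and a score from the authors' caller. The scale of the deposited scores is not stated. Scores started at 50.03 and 50.09 in the replicate lists, where 45 and 9 regions stood at exactly 3100, and at 1.32 in the series-wide list. The scores were therefore used to rank and compare regions within a list, and between lists in the correlations and the ranks of regions shared by the replicates. No file of the input libraries and no read counts were used here, so the depth of each library is unknown and intervals cover only the counting error of regions.

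All positions are WS220 and 1-based. The span of each chromosome was taken as the highest region end over the 3 lists, since no WS220 chromosome lengths were used here. These spans differed from the last gene end in a RefSeq gene table of another assembly, WBcel235, by -0.696% on chromosome II and by at most 0.00692% on the others. Peak midpoints of the series-wide list were offset from those of replicate 1 by medians of -8 to -27.5 bp on the left and right sides of the 6 nuclear chromosomes, with no build-sized drift towards the chromosome ends. Positions were not carried between builds. Regions are therefore named by position alone, and the tests planned on promoters, tRNA genes, fixed gene lists and the recruitment motif of the dosage compensation complex were not run. From the WBcel235 table only the number of genes per chromosome was taken. Mitochondrial regions were set apart from every comparison of X with the autosomes.

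The density of peaks per Mb on X was compared with that on chromosomes I to V by a two-sided exact binomial test, with an exact conditional 95% interval of the ratio. That test takes regions as independent counts, so it was repeated with 1-Mb bins as units (permutation test, 100000 resamples, two-sided). The density of single chromosomes has an exact Poisson 95% interval, and the evenness of the autosomes was tested with 100000 multinomial draws. Overlap between lists required 1 bp and was compared with 10000 placements of the replicate 2 regions at random within their chromosome (one-sided). The other overlaps between lists were set beside the mean of a smaller number of such placements, without a test. Medians of score and width were compared by permutation tests (100000 resamples, two-sided) with bootstrap 95% intervals. Shares of X and autosomal peaks were compared by Fisher's exact test, and those of the 6 list overlaps were adjusted by Benjamini-Hochberg. The share of midpoints in the central 33.3% of each chromosome was compared with that share by a two-sided exact binomial test. Scores of shared regions were correlated across regions, which are not independent replicates, with permutation p-values.

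The tests of density, covered bases, replicate overlap, score, width, central share and score correlation, their alternatives and the rule for naming peaks were fixed before the data were examined. The rule took the 12 X peaks and the 12 autosomal peaks with the highest series-wide score among those that overlapped a region in both replicate lists. The alternatives fixed with them were the higher-scoring part of each list, each replicate list alone, the peaks present in both, merging of peaks within 1 kb, the number of protein-coding genes in place of length, a 50% overlap and replicate 1 reduced to the size of replicate 2. Added after seeing the data were merging within 10 kb, leaving out regions over 2 kb, the density ratio in replicate 1 reduced to the size of replicate 2, X against each autosome alone, and the bins. Fisher's tests of X against the autosomes, the test of evenness, the shares by score class and the width tests on the named peaks were also added after the lists had been looked over, as were the tests on spacing and on the widths of the highest-scoring peaks. The statistics were tested on simulated lists. At the size of the series-wide list and a true ratio of 3, the mean estimate was 2.999, 94.5% of the intervals held the true value, and 4.52% of unenriched lists fell under the 0.05 threshold. These density simulations drew regions as independent counts, as the test assumes, so they do not cover clustered regions. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.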

Results

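The genomic distribution of MIX-1 was profiled by ChIP-seq in wild-type mixed-stage embryos of C. elegans. MIX-1 is the SMC2-type ATPase of this nematode. It is shared by the mitotic and meiotic condensins and by the condensin of the dosage compensation complex, which binds the X chromosomes of hermaphrodites and lowers their expression. The series-wide list held 2705 regions, of which 1076 lay on X, 1619 on chromosomes I to V and 10 on the mitochondrial genome. The list of replicate 1 held 2310 regions and that of replicate 2 held 706. Median region width was 258 bp in the series-wide list, 378 bp in replicate 1 and 434.5 bp in replicate 2, and the nuclear regions covered 1033, 1245 and 515.3 kb. The sequencing depth behind the lists is unknown, so a difference in the number of regions between the replicates cannot be read as a difference in binding.

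The first comparison was between X and the autosomes, since MIX-1 serves both an X-specific and chromosome-wide condensins. MIX-1 peaks were 3.09 times as dense on X as on chromosomes I to V in the series-wide list (95% interval 2.86 to 3.34), at 60.7 against 19.6 peaks per Mb. X held 39.9% of the nuclear peaks (exact 95% interval 38.1 to 41.8) and 17.7% of the nuclear span. Each replicate list on its own gave an excess on X, with a ratio of 2.74 (2.52 to 2.99) in replicate 1 and 3.30 (2.83 to 3.84) in replicate 2, or 3.02 ± 0.394 (SD, n = 2). Replicate 1 reduced to the size of replicate 2 gave 3.46 (2.97 to 4.02), so this SD depends on the length of the lists. The autosomes nevertheless carried most of the peaks, with 1450 of 2305 nuclear regions in replicate 1 and 413 of 706 in replicate 2.

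The excess was present along the whole of X. Across 17 bins of 1 Mb, X had 60.8 ± 13.4 series-wide peaks per bin (SD over bins, range 44 to 94), against 19.4 ± 8.56 over 80 autosomal bins (range 7 to 64), and all 17 X bins lay above the autosomal median in each of the 3 lists. The exact binomial test gave p = 3.9e-161 for the series-wide list, 8.9e-108 for replicate 1 and 2.7e-49 for replicate 2. With bins as units the permutation p was 1e-05 in each list, the smallest that 100000 resamples can give. These tests measure the spread of regions or bins within a list, and with 2 libraries no test across replicates was made.

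**Figure D1:**
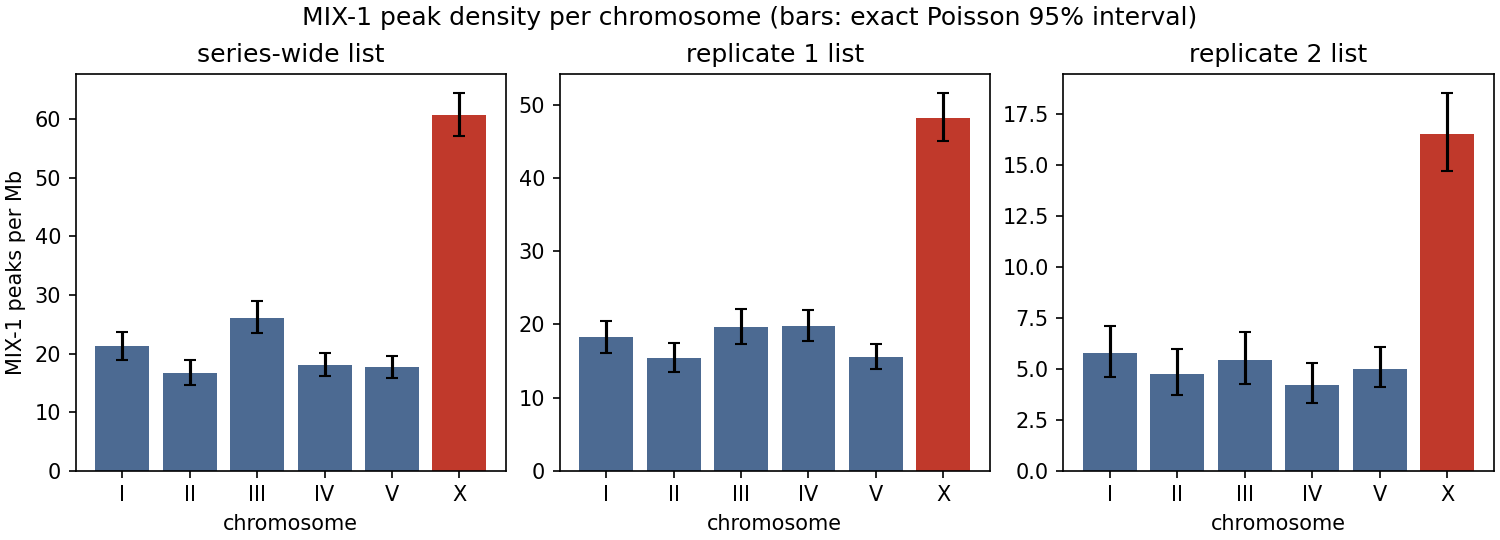
MIX-1 peaks per Mb on each nuclear chromosome (x axis) in the series-wide list and in the lists of both replicates, with exact Poisson 95% intervals; the vertical scales differ between panels. X stands above every autosome in each panel, at 60.7, 48.3 and 16.5 peaks per Mb.

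Among the autosomes, chromosome III had the highest series-wide density, at 26.1 peaks per Mb (95% Poisson interval 23.5 to 29.0), and chromosome II the lowest, at 16.7 (14.7 to 18.9). X exceeded chromosome III by 2.33 times (2.06 to 2.63) and chromosome II by 3.64 times (3.17 to 4.19). The autosomes differed beyond counting error in the series-wide list (Monte Carlo estimate of the exact multinomial p = 1e-05, the smallest the draws can give) and in replicate 1 (p = 0.00109), but not detectably in replicate 2 (p = 0.332). The order of the autosomes was not the same in the replicates. Chromosome IV, at 19.8 peaks per Mb, and chromosome III, at 19.6, were highest in replicate 1, and chromosome I, at 5.77, was highest in replicate 2.

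Peaks covered 2.33% of X and 0.751% of the autosomes in the series-wide list, a ratio of 3.11, from 413.4 kb on X and 619.2 kb on the autosomes. The corresponding ratio was 2.47 in replicate 1, from 432.1 and 813.2 kb, and 2.33 in replicate 2, from 171.9 and 343.4 kb. The mean width of autosomal regions exceeded that of X regions in the replicate lists, at 560.8 against 505.3 bp in replicate 1 and 831.4 against 586.7 bp in replicate 2. In the series-wide list these means were 382.5 and 384.2 bp.

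By series-wide score, the highest-scoring MIX-1 sites on X formed wide peaks at intervals along the chromosome. The highest score on X, 179.7, belonged to a peak of 1967 bp at X 11935924 to 11937890. It was followed by X 2995863 to 2997465 with a score of 178.9, X 9465282 to 9466317 with 176.8, X 8035793 to 8037436 with 175.6 and X 11093678 to 11094609 with 173.1. The next were X 14525268 to 14526824 with a score of 172.6, X 4208524 to 4210462 with 170.4 and X 6295455 to 6297431 with 161.4. The remaining 4 of the 12 named X peaks lay at 0.807, 12.4, 13.7 and 16.1 Mb, with scores of 137.5 to 154.2. In replicate 1, 11 of the 12 scored 3100, the value at which that list's scores piled up, and in replicate 2 their scores ran from 933.9 to 3100. Whether 3100 was measured or set by the caller is not stated, so regions at that score were not ranked among themselves; the highest scores of the replicate lists were 3113 and 3145. Gene annotation of WS220 was not used here, so the features under these positions are not given.

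The 12 named autosomal peaks, the strongest by series-wide score, were narrower, and 7 of them lay on chromosome II. In replicate 1, 3 of these 12 scored 3100, against 11 of the 12 named X peaks, so the named sets were not alike in replicate 1 score. The naming went by series-wide score, and replicate 1 held 46 regions at or above 3100. These counts therefore do not show how its highest-scoring regions divide between X and the autosomes. Of the 231 regions in its highest-scoring 10%, 91 lay on X. II 10033378 to 10033978 and II 10034559 to 10035035 lay within 1 kb of each other. II 5346365 to 5346895 and II 5350228 to 5350656 lay within 10 kb of each other. These neighbours were counted as separate peaks. The highest score of the whole list belonged to II 5844409 to 5845362, a peak of 954 bp that scored 3100 in both replicates. The other named peaks that scored 3100 in both replicates were II 5543254 to 5544422, with a series-wide score of 156.7, and I 4171786 to 4172645, with 124.0. Next by score among the rest were III 4568473 to 4568875 with 157.4, II 5350228 to 5350656 with 137.1, III 10460985 to 10461435 with 134.8 and II 7708487 to 7708907 with 130.5. Of the 12, none lay on chromosome IV and 1 lay on chromosome V, at V 14038377 to 14038962.

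The 12 named X peaks had a median width of 1580 bp (range 932 to 2063) and the 12 autosomal peaks 504 bp (range 403 to 1169), a difference of 1076 bp (permutation test, two-sided p = 0.00018). The same sites differed in replicate 1, with medians of 1388 and 612.5 bp (permutation p = 0.00015), and in replicate 2, with 1090 and 513.5 bp (permutation p = 0.0284). These width tests on the named peaks were chosen after the values had been seen, and they took the neighbouring peaks on chromosome II as separate units. The 3 autosomal peaks at 3100 in both replicates measured 860 to 1169 bp, and the other 9 measured 403 to 601 bp and scored 270.8 to 587.7 in replicate 2.

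**Figure D2:**
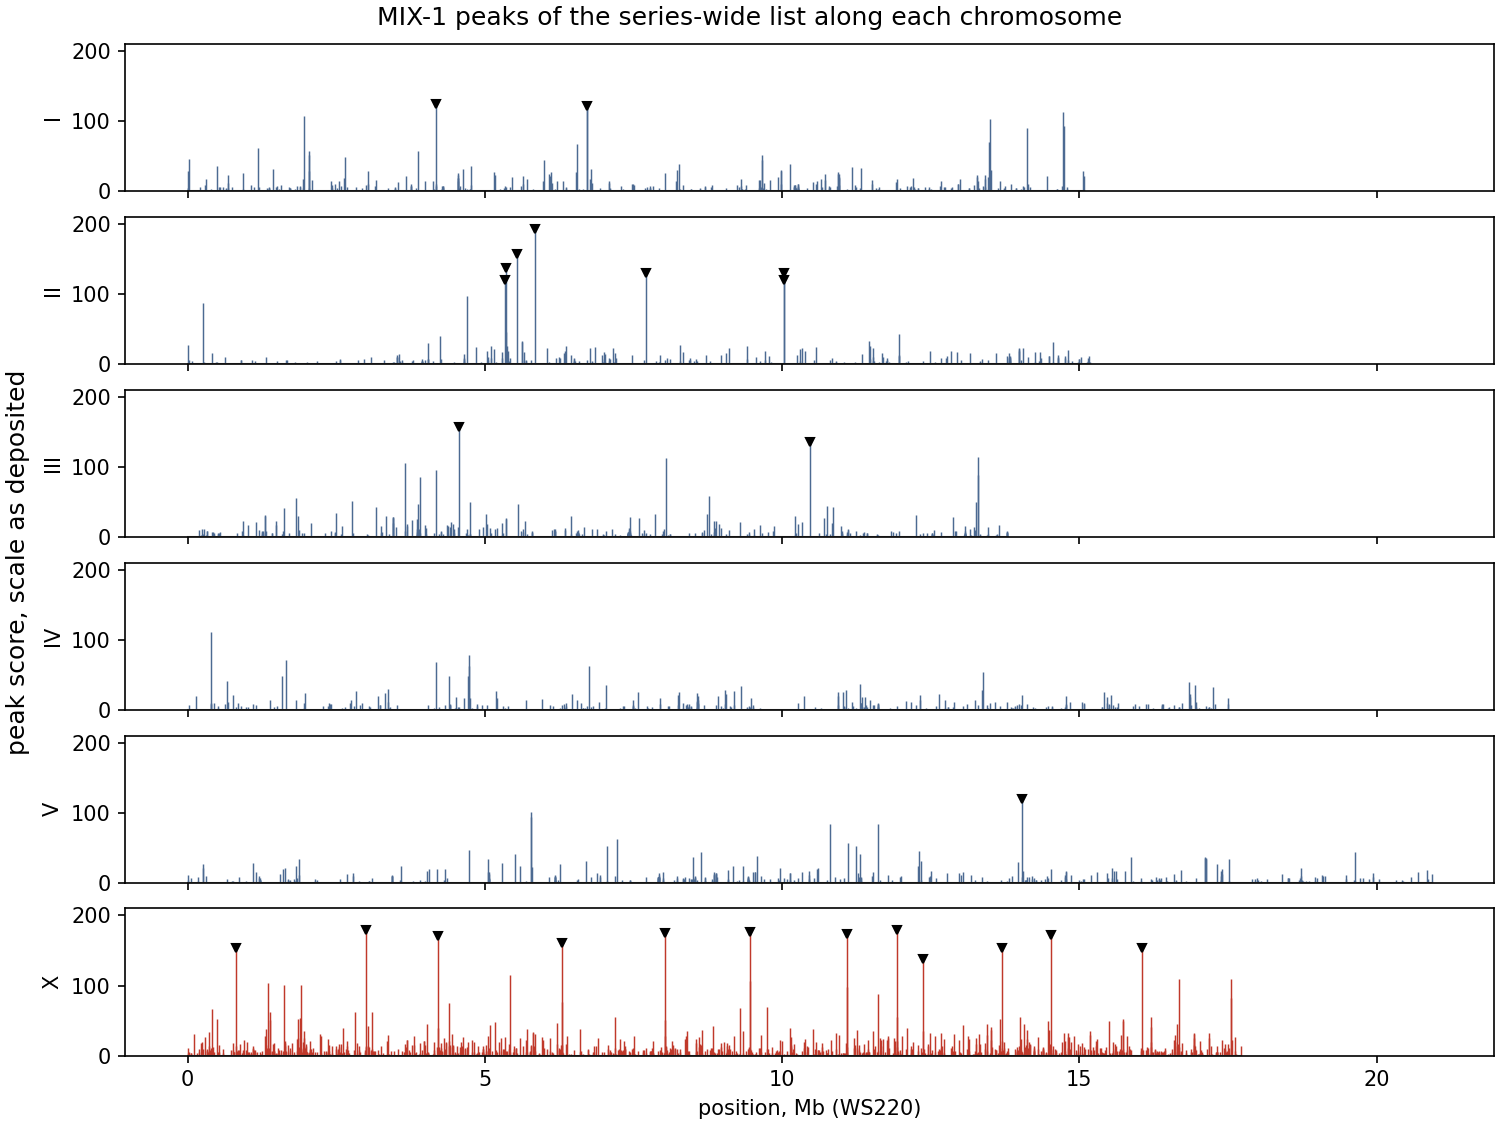
Series-wide MIX-1 peaks along the 6 nuclear chromosomes (x axis, Mb in WS220; y axis, deposited peak score), with triangles on the 12 named X peaks and the 12 named autosomal peaks. The named X peaks run from 0.807 to 16.1 Mb, and 7 of the named autosomal peaks stand on chromosome II, some of them within 10 kb of each other.

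Over all peaks, the difference in score between X and the autosomes was small and did not pass the test in replicate 2. The median series-wide score was 7.73 on X and 6.86 on the autosomes, a difference of 0.865 (bootstrap 95% interval 0.32 to 1.55, permutation p = 0.00227). In replicate 1 the medians were 130.5 and 110.1 (permutation p = 0.00021), whereas in replicate 2 they were 112.2 and 117.4, with an interval of the difference of -21.9 to 14.7 (permutation p = 0.504). Within the higher-scoring part of the series-wide list the score difference was -0.055 (permutation p = 0.805), and among the 601 peaks found in both replicate lists it was 3.04 (permutation p = 0.033). In width, X peaks exceeded autosomal peaks by 37 bp in the series-wide list (23 to 50 bp, permutation p = 1e-05, the smallest possible) and by 57 bp in replicate 1 (27 to 79.5 bp, permutation p = 7e-05). In replicate 2 the difference was -12 bp (-67 to 31 bp, permutation p = 0.625), and among the peaks found in both replicate lists it was 21.5 bp (permutation p = 0.33). In the higher-scoring part of the series-wide list the width difference was 39.5 bp (permutation p = 1e-05, the smallest possible).

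**Figure D3:**
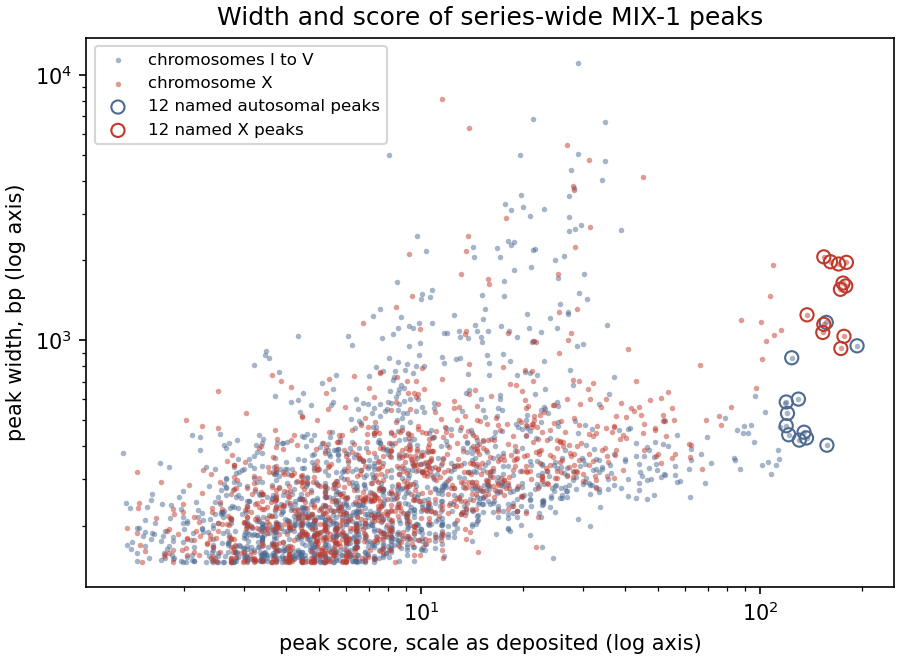
Width in bp (y axis) against deposited score (x axis) of series-wide peaks on X and on chromosomes I to V, both on log axes, with rings around the 12 named peaks of each class. The named X peaks measure 932 to 2063 bp and the named autosomal peaks 403 to 1169 bp.

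The replicate lists were compared by overlap, the check that lists of regions allow. Of the 706 regions of replicate 2, 603 (85.4%) overlapped a region of replicate 1, against a mean of 3.31% and a maximum of 5.52% over 10000 random placements. The one-sided p from these placements was 1e-04, the smallest they can give. In the other direction 615 of the 2305 nuclear regions of replicate 1 (26.7%) met a region of replicate 2, so most regions of the longer list had no counterpart. With replicate 1 reduced to its 706 highest-scoring regions, 63.3% of replicate 2 regions overlapped it. Overlap between the replicates was higher on X than on the autosomes, at 89.4% against 82.6% of replicate 2 regions (Fisher's exact test, adjusted p = 0.0189) and at 30.5% against 24.4% of replicate 1 regions (adjusted p = 0.00305). Random placement also gave more overlap on X, at 4.95% against 2.20% of replicate 2 regions and 1.72% against 0.668% of replicate 1 regions, which these tests do not take into account. Series-wide peaks showed no detectable difference, at 66.0% against 63.1% overlapping replicate 1 (Fisher's exact test, adjusted p = 0.155) and 25.7% against 25.5% overlapping replicate 2 (adjusted p = 0.893). Of replicate 2 regions, 98.3% on X and 92.01% on the autosomes overlapped a series-wide peak (Fisher's exact test, adjusted p = 0.000449).

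Scores of the 603 shared regions rose together, with Spearman rho = 0.599 and Pearson r = 0.69 across regions (permutation p = 1e-05 for each, the smallest possible). Over the 556 shared regions below 3100 in both lists, Pearson r was 0.56.

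Of the 2695 nuclear series-wide peaks, 601 (22.3%) overlapped regions of both replicates, 1130 (41.9%) only replicate 1, 89 (3.30%) only replicate 2 and 875 (32.5%) neither. Their median scores were 21.8, 6.90, 8.18 and 5.03. X held 41.9% of the peaks found in both replicates (exact 95% interval 38.0 to 46.0), 40.5% of those found only in replicate 1 (37.7 to 43.5), 28.1% of those found only in replicate 2 (19.1 to 38.6) and 38.97% of those found in neither (35.7 to 42.3). In the 10% of the series-wide list with the highest scores, 100% of peaks met replicate 1 and 87.0% met replicate 2, and in the lowest 10% these shares were 42.4% and 4.83%. The X share was 44.8% in the highest 10% and 35.7% in the lowest.

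**Figure D4:**
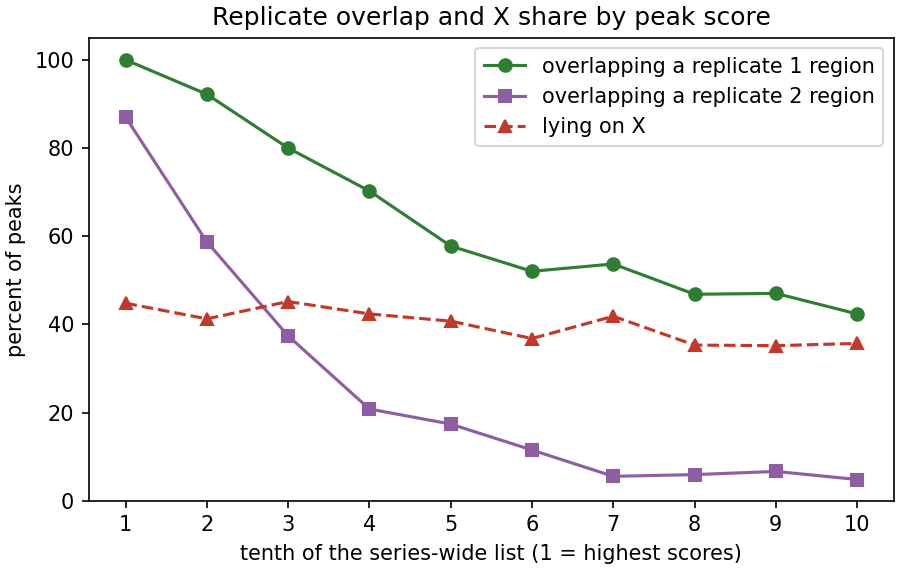
Percent of series-wide peaks (y axis) that overlap a region of replicate 1 or of replicate 2, or that lie on X, in 10 classes of equal size ordered by score (x axis, 1 = highest). Overlap with replicate 2 is 87.0% in class 1 and 4.83% in class 10, and the X share is 44.8% and 35.7%. The X share does not fall steadily: it is highest in class 3, at 45.2%, and lowest in class 9, at 35.2%.

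Along the chromosomes, series-wide X peaks were somewhat fewer in the central 33.3% of the chromosome than length alone gives, a difference that did not pass the test in every list or subset. In the series-wide list 29.1% of X peaks (exact 95% interval 26.4 to 31.9, exact binomial p = 0.00323) and 36.5% of autosomal peaks (34.2 to 38.9, exact binomial p = 0.00716) had their midpoint there. X and the autosomes differed in this list (Fisher's exact p = 6.4e-05), but the difference missed the threshold in replicate 1 (p = 0.0623) and replicate 2 (p = 0.192). The X share was 28.7% in replicate 1 (exact binomial p = 0.00368) and 29.7% in replicate 2 (exact p = 0.194). It was 29.8% in the higher-scoring part of the series-wide list (exact p = 0.0705) and 28.97% among peaks found in both replicates (exact p = 0.16), neither past the threshold. The autosomal share was 32.4% in replicate 1 (exact p = 0.469) and 34.6% in replicate 2 (exact p = 0.602), so the autosomal excess in the centre did not pass the test in either replicate. Single autosomes went both ways, in tests that were not among those fixed beforehand and whose p-values were not adjusted for their number. Chromosome I had 28.75% of its series-wide peaks (exact p = 0.0856) and 23.6% of its replicate 1 peaks (exact p = 0.000532) in the centre, both below the X shares, whereas chromosome III had 40% (exact p = 0.00852) and 42.2% (exact p = 0.00237). Chromosomes IV and V were also above 33.3% in the series-wide list, at 38.9% (exact p = 0.0368) and 38.6% (exact p = 0.0315), but not past the threshold in replicate 1, at 31.99% (exact p = 0.609) and 34.5% (exact p = 0.681). In replicate 2 the shares of chromosomes I and III were 29.9% and 32% (exact p = 0.57 and 0.903).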

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

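The values by score for the mitochondrial regions were chosen after the result was seen. The ratios by score and by replicate were set before the data were examined, but were taken as tests of these explanations only after their values had been seen. Merging within 10 kb and the tests on width were added later: what each would show was written down before its own value was known, but after the scores, widths and positions of the highest peaks had been looked over.

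The mitochondrial genome, which no comparison used, held 10 regions in the series-wide list, 5 in replicate 1 and 0 in replicate 2, in lists that differ in size and whose depth is unknown. The 5 regions of replicate 1 covered 97.8% of the 13.03 kb spanned by mitochondrial regions, with scores of 80.0 to 1788. A shorter replicate 2 list is a candidate explanation: of the 1558 nuclear replicate 1 regions that scored at least 80.0, 37.0% (34.6 to 39.5) were met in replicate 2, between the bounds set for and against it, so the test did not decide. Of nuclear regions within 25% of the score of each mitochondrial region, 93.1%, 87.8%, 87.2%, 57.6% and 8.61% were met, from the highest score to the lowest. The chance that all 5 would be missed was 0.000419 if they were independent and 0.069 for the highest alone; adjacent stretches of one molecule are not independent, which keeps the question open, and no biological explanation was tested.

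The density of MIX-1 peaks on X may have technical sources, and 3 were tested. Weak calls as its source would bring the ratio near 1 among higher scores, but the lower 95% bound in the higher-scoring part of the list was 3.13. Splitting of broad stretches into calls within 10 kb of each other would remove it on merging. After that merging the ratio fell from 3.09 to 2.42, with a lower bound of 2.18. Such splitting is therefore not the whole source and may account for part, and stretches split at wider gaps were not tested. Calls of 1 library would leave replicate 2 without an excess, but its lower bound was 2.83. Copy number and mappability of X, for which input reads would be needed, were not tested and stay open beside the X-specific condensin that contains MIX-1, which is a hypothesis here since the series has no sample lacking that complex.

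By series-wide score, high-scoring X peaks were wider than high-scoring autosomal peaks. Medians were 498 and 362.5 bp in the highest-scoring 10% of the series-wide list (121 and 148 peaks, difference 135.5 bp, 78 to 192). A difference in series-wide score could produce this, but over 112 pairs matched within 10% of that score the median difference was 122.5 bp, with a lower 95% bound of 70 bp; the pairs were not matched on replicate scores, which differed among the named peaks in replicate 2 (medians 2755 on X and 439.2 on the autosomes, permutation p = 0.0449), so a difference in strength stays open. Splitting of autosomal stretches by the caller could too, but would leave autosomal peaks wider on merging, and after merging within 1 kb the medians were 549 bp on X and 356 bp on the autosomes; the lower bound of the difference, 119.5 bp, is raised by the merging of X peaks, which lie closer together. In replicate 1, whose list names another caller version, the regions meeting that 10% differed by 66 bp with a lower bound of 37 bp. The series-wide scores chose these regions, so the test cannot exclude the series-wide caller as the source. In 5 equal classes of replicate 1 scores, X regions were narrower in the highest class (medians 667.5 and 685 bp) and the next (481 and 508 bp). They were wider in the middle class (374.5 and 347 bp). Below it the medians were 247 and 249 bp, then 196 and 188 bp. A lower bound above 100 bp had been set beforehand as the value that would exclude the score difference, the splitting or the series-wide caller. The score matching and replicate 1 did not reach it. A looser criterion, a bound above 0, was adopted for both after those values were seen, because a whole source needs a difference of 0. For replicate 1 it decides nothing, since the series-wide scores chose the regions.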

How the results depend on the processing

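Of 41 alternatives run over 8 results, 27 kept the direction and the side of the threshold or, for the covered-base ratio, which has no test, moved by less than the spread between replicates, and the density ratio kept direction and side under all 15 of its alternatives, from 2.33 (against chromosome III alone) to 4.20 (per protein-coding gene). The covered-base ratio moved from 3.11 to 3.25 in the higher-scoring part of the list, to 3.37 without regions over 2 kb, and to 2.33 and 2.47 in the replicate 2 and replicate 1 lists alone. The score difference, 0.865, reversed to -0.055 in the higher-scoring part, and leaving out a replicate gave -5.24 (replicate 2 alone) to 20.38 (replicate 1 alone), on another score scale. The width difference, 37 bp, ranged from -12 to 57 bp in the single replicate lists and was 21.5 bp, no longer past the threshold, for peaks in both, where fewer peaks were tested. The central share of X, 29.1%, was 29.8% in the higher-scoring part and 29.0% for peaks in both, no longer past the threshold, and 28.7% to 29.7% in the single lists. The autosomal central share, 36.5%, was 35.0% for peaks in both and 32.4% to 34.6% in the single lists, reversed in replicate 1 alone. Where no cause is given, the cause was not tested. No paired analysis was possible because no file of the input libraries that share the replicate numbers was used here. The alternatives on promoters, tRNA genes, gene lists, the motif and the central share expected from gene starts were not run, since no annotation or genome of WS220 was used. Read depth, and with it the lowest enrichment each list could hold, is unknown.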

Other observations

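The tests of X against the autosomes by overlap, within score classes, on the upper and lower parts of the list, on rank and on spacing were chosen after the lists had been seen, and the score limit of 100 for spacing was set after the strongest X positions had been looked over.

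Regions of 4 kb or more that were present in all 3 lists lay on 6 chromosomes. The widest, I 15060242 to 15071350, measured 11109 bp in the series-wide list, 11115 bp in replicate 1 and 11148 bp in replicate 2. It lies at the right end of chromosome I, where the tandem rRNA gene array of this species is found. No test of position against genes was made, and without input reads the copy number under the wide regions was not checked. The others included V 10605627 to 10612454 (6828 bp) and V 17119924 to 17126596 (6673 bp). On X they were X 10361059 to 10369200 (8142 bp), X 289830 to 295291 (5462 bp), X 109487 to 114282 (4796 bp) and X 4025950 to 4030086 (4137 bp). Their series-wide scores, 8.05 to 45.2 over all 11 regions, were below those of every named peak.

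The series-wide list took up X regions of replicate 1 more often than autosomal ones, at 84.2% against 67.2% (Fisher's exact test, adjusted p = 4.96e-19), where random placement gave 5.14% against 1.74%. The gap was present within each of 5 equal classes of replicate 1 scores. In the middle class, with scores of 92.95 to 147.8, it was 91.8% of 158 X regions against 64.7% of 303 autosomal regions (Fisher's exact p = 3.5e-11), and in the lowest class it was 53.6% against 43.2% (p = 0.0372). The X share of series-wide peaks was 42.9% in the higher-scoring part and 36.9% in the lower (Fisher's exact p = 0.00165). In replicate 2 the lowest-scoring 10% held the highest X share of that list, 41 of 70 regions (58.6%). Among regions shared by the replicates, the rank in replicate 2 less that in replicate 1 did not differ detectably between X and the autosomes (difference 1.66 percentile points, -1.04 to 4.15, permutation p = 0.286).

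Strong MIX-1 sites on X may be spaced more evenly than at random. The 18 X loci with a series-wide score of at least 100, after joining peaks within 10 kb, had a median gap of 0.867 Mb (0.282 to 1.74 Mb). The coefficient of variation of their gaps was 0.47, against a median of 0.919 over 100000 random placements, of which 0.064% were as low. With a score of at least 75 there were 20 loci and 0.464% of placements were as low, but with 50 there were 35 loci and 16.5% were as low. For the 18 highest X loci of replicate 2 the share was 0.904%, and for the 21 X loci of replicate 1 at or above 3100, all used because their order is not known, it was 3.17%. The evenness is thus a hypothesis about the strongest sites, found at the higher score limits and not at 50, and the distribution of mappable sequence on X was not used in the placements.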
